A study of Homo sapiens with 23 samples.

How the data were processed

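The study sequenced total RNA from slices of archived, formalin-fixed vulvar squamous cell carcinoma, 12 HPV-positive and 11 HPV-negative per the labels. Libraries were made with a ribosomal RNA depletion kit, per the labels' protocols. Reads were trimmed with Trim Galore, aligned with STAR 2.7.2b and handled with SAMtools 1.9, and HTSeq is named as the counter, per the submitters' processing notes. The genome build was hg38, per the submitters' processing notes. The annotation release and the strand setting of the counting are not given in the sources used here, so reads of a gene and of an overlapping or antisense partner cannot be told apart with certainty. The deposited values are raw counts of reads per gene, whole numbers in 23 columns, each matched to its tumour by the number that ends the sample title, and 0 columns were left unmapped. The table held 67071 gene rows and 5 summary rows, and the summary rows were kept out of library sizes and tests.

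The summary rows took most of the reads. Reads in no annotated feature made up between 47.5% and 69.0% of all reads per tumour, unaligned reads between 3.46% and 8.55%, reads aligned to several places between 3.43% and 9.81%, and ambiguous reads between 1.07% and 3.68%. Reads of low alignment quality made up at most 0.0534%. Between 22.4% and 36.9% of reads were counted in genes, which left 7358592 to 14353034 counts per tumour. The highest correlation of log2 CPM between any 2 tumours was 0.952 and the lowest 0.830, so no library pair looked like duplicates. These reads carry no molecular identifiers, so counting error is not independent of amplification. The biological coefficient of variation between tumours of a group was 0.537.

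Symbols came from the supplied gene table and matched 60415 of the 67071 IDs, and places came from GENCODE release 29 for 58541 IDs. XIST and genes of chromosome Y were left out of the tests but stayed in the library sizes. Genes were filtered with filterByExpr and scaled with TMM factors, which lay between 0.776 and 1.11. The main test was edgeR 4.0.16 with glmQLFit (robust) and glmQLFTest, HPV-positive against HPV-negative with no covariate, and Benjamini-Hochberg adjustment at 0.05. The standard error of a fold change was derived from the F statistic. Fold changes, CPM values and list scores were computed here from the deposited counts.

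Gene lists, 37 in all, and the alternatives were fixed before the data were examined, except where an alternative is named as added. Lists with at least 5 tested members, 35 in all, were tested with camera (limma 3.58.1) on voom values at the preset correlation of 0.01, and again with the correlation estimated for each list and with fry. A further permutation test on the mean log2 CPM of each list was added after seeing the data. CDKN2A was compared by a permutation test with 100000 resamples on log2(CPM + 1). The share of variance between groups and the 2 relations between list scores used 100000 resamples as well, on log2 CPM with a prior count of 2. A score is the mean over members of the z-scored log2 CPM.

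Genes named in the text follow a rule set beforehand. It takes the 10 genes per direction with the smallest p among those passing the adjusted threshold with at least 1 CPM in the higher group, which gave 0 genes. It adds CDKN2A, CDKN1A, MDM2, MKI67, EGFR, CCND1, CD274 and PIK3CA whatever their result, and 2 to 4 members with the smallest p in each list described. A few genes that the rule takes and 1 of the lists are not reported here. Genes named beyond this rule are stated to have been chosen after their values were seen.

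Alternatives were DESeq2 1.42.0, limma-voom with sample quality weights, a rank test per gene, DESeq2 size factors and upper quartile factors in edgeR, no filter, a filter of 1 CPM in at least 11 tumours, glmTreat at 1.5-fold, and robust estimation turned off. The rank test gives no fold, so the difference of group means of log2 CPM stands beside it. Covariates tried in turn were 1 surrogate variable (sva 3.50.0), log2 library size and the T and NK cell score. Alternatives added after seeing the data were the percent of reads in genes as a covariate, leaving out the 2 tumours with over 8% unaligned reads, and leaving out each tumour in turn. The tests were checked on simulated counts for 19027 genes with 200 genes changed 2-fold or 4-fold. For these, edgeR recovered 44% and 89%, DESeq2 50% and 93%, limma-voom 44% and 80%, and the rank test 23% and 57%. False calls numbered 3, 34, 8 and 2 in that order. The simulated genes were drawn independently of each other at edgeR's dispersions, and changes were planted only in genes averaging at least 1 CPM. Statistics outside R 4.3.3 used scipy 1.17.1 and numpy 2.4.6.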

Results

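Total RNA was sequenced from formalin-fixed, paraffin-embedded blocks of invasive vulvar squamous cell carcinoma, a keratinocyte cancer that arises with or without human papillomavirus (HPV). The labels place 12 tumours in an HPV-positive group and 11 in an HPV-negative group, without saying how HPV status was determined. The deposited counts per gene summed to between 7358592 and 14353034 per tumour, with a median of 10241441. HPV-positive libraries held 11228741 ± 2118107 counts (SD, n = 12) and HPV-negative libraries 9715277 ± 1930895 (SD, n = 11), a difference within the spread between tumours (two-sided permutation test, p = 0.0898). The labels do not say whether every tumour came from a different patient, so the p-values given here measure the spread between these samples. No batch, date or run is given in the labels used here. The comparison asks how the transcriptome of HPV-positive tumours differs from that of HPV-negative tumours. Fold changes are log2 of HPV-positive over HPV-negative throughout, and levels are CPM, counts scaled to the effective library size.

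By camera with its preset correlation, gene lists of HPV-driven carcinomas and of DNA replication were higher in HPV-positive tumours. The list of neutrophil markers and chemoattractants was lower. None of these 3 calls held with an estimated correlation (adjusted p = 0.437, 0.437 and 0.286), and none of the 19027 genes tested passed an adjusted p of 0.05 on its own with edgeR. SYCP2, a protein of the meiotic synaptonemal complex, averaged 69.6 ± 58.5 CPM (SD, n = 12) in HPV-positive tumours against 10.6 ± 15.4 CPM (SD, n = 11) in HPV-negative tumours. RFC5, a subunit of the clamp loader of DNA replication, averaged 24.4 CPM against 13.6 CPM. CXCL8, the neutrophil chemoattractant interleukin-8, averaged 32.6 CPM against 111 CPM. With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 0 genes were higher and 0 lower in HPV-positive tumours, while 1692 genes had an unadjusted p under 0.05. DESeq2 called 35 genes higher and 8 lower at the same adjusted threshold. In simulated counts with these library sizes, 200 of 19027 genes were changed. Of those changed 2-fold and 4-fold, edgeR recovered 44% and 89%, and DESeq2 50% and 93%. Beside these, DESeq2 made 34 false calls where edgeR made 3. The false calls belong to the simulation and are not a count of false genes among the 35 and 8. The simulated genes were drawn independently of each other at edgeR's dispersions, so these rates need not hold for the real tumours.

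PLEKHG4, a guanine nucleotide exchange factor on chromosome 16, had the smallest p of all genes tested and was chosen after its values were seen. It averaged 45.4 ± 24.7 CPM in HPV-positive tumours and 13.2 ± 7.19 CPM in HPV-negative tumours, a log2 fold change of 1.78 ± 0.33 (SE), and its adjusted p was 0.214 with edgeR. All 12 HPV-positive tumours lay above the HPV-negative median of PLEKHG4. Among the genes that DESeq2 called, and also chosen after their values were seen, STMN1 encodes a microtubule-destabilising protein and PHGDH the first enzyme of serine synthesis. STMN1 averaged 125.2 CPM in HPV-positive and 51.8 CPM in HPV-negative tumours, and PHGDH 72.4 and 20.4 CPM. The log2 fold change of PHGDH was 1.83, and it was 1.16 with quality weights and 1.15 with 1 surrogate variable. From the 8 genes called lower by DESeq2, the myeloid receptor CD300E and the cytokine TNFSF14 were also chosen after their values were seen. CD300E averaged 7.76 ± 6.0 CPM (SD) against 27.0 ± 19.2 CPM, and TNFSF14 5.25 ± 1.8 CPM against 14.2 ± 13.6 CPM. Their adjusted p with edgeR was 0.303 and 0.325.

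The list of meiotic, germline and other genes known from HPV-driven carcinomas, called the meiotic list below, was higher by camera with its preset correlation only. Of its 14 members 8 were tested. All 8 had a positive fold change, with a median of 1.88, and 4 passed adjusted over the list alone against 0 over all genes tested. These were the potassium channel subunit KCNS1 with a log2 fold change of 3.09 ± 0.76 (SE), SYCP2 with 2.72 ± 0.70, RIBC2 with 1.98 ± 0.55 and SYNGR3 with 1.83 ± 0.64. KCNS1 lies on chromosome 20 from 45092310 to 45101112 and SYCP2 on the same chromosome from 59863563 to 59933655 (GRCh38, GENCODE release 29, minus strand). The groups overlapped, since SYCP2 ranged from 4.49 to 170.2 CPM in HPV-positive and from 0.768 to 42.9 CPM in HPV-negative tumours. The list mean lay above the HPV-negative median in 11 of 12 HPV-positive tumours. The list passed camera with its preset correlation (adjusted p = 9.5e-05), and its adjusted p = 0.437 with an estimated correlation. Relabelling the tumours gave p = 0.0112 for the list mean, or 0.122 after Benjamini-Hochberg adjustment over 35 lists.

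**Figure D1:**
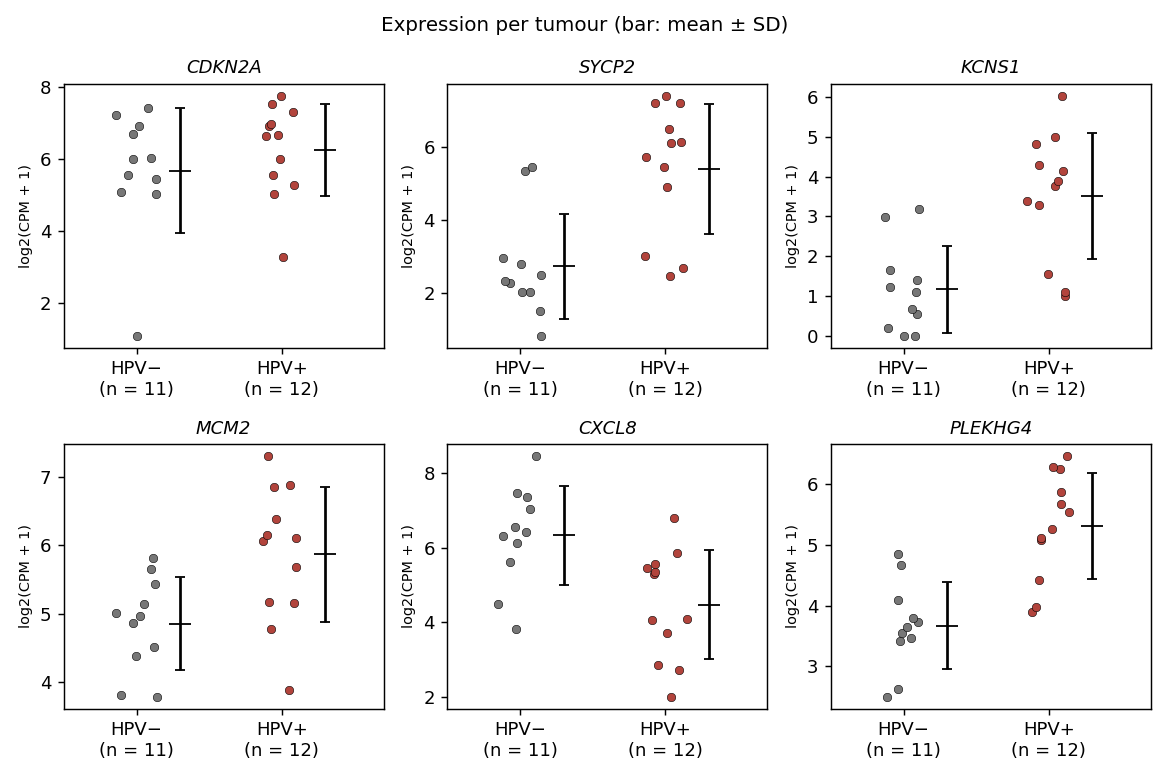
Expression of 6 genes per tumour as log2(CPM + 1) on the vertical axis, with HPV-negative tumours in grey (n = 11), HPV-positive tumours in red (n = 12) and bars for the mean and SD. SYCP2 ranged from 4.49 to 170.2 CPM in HPV-positive tumours and from 0.768 to 42.9 CPM in HPV-negative tumours, and CDKN2A overlapped over nearly the whole range.

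Genes of DNA replication, whose expression the RB and E2F proteins help control, were higher by a median of 0.55 on the log2 scale. Of 44 members of the replication licensing and fork list, 43 had a positive fold change and 28 an unadjusted p under 0.05. Adjusted over the list alone 22 passed, all higher, and 0 passed over all genes tested. RFC5 had a log2 fold change of 0.85 ± 0.21 (SE), the single-strand binding protein subunit RPA2 0.93 ± 0.23, the replicative helicase subunit MCM2 1.17 ± 0.33 and the helicase cofactor GINS3 0.73 ± 0.21. The list passed camera with the preset correlation (adjusted p = 1.0e-15), and its adjusted p = 0.437 with an estimated correlation. The mean log2 CPM of its members was 4.79 ± 0.56 (SD, n = 12) in HPV-positive and 4.28 ± 0.29 (SD, n = 11) in HPV-negative tumours (permutation test, p = 0.0137, adjusted p = 0.122), and 10 of 12 HPV-positive tumours lay above the HPV-negative median. The share of reads counted in genes was 31.6 ± 3.29% (SD, n = 12) in HPV-positive and 28.5 ± 4.58% (SD, n = 11) in HPV-negative tumours (permutation test, p = 0.0797). It serves here as a rough stand-in for RNA quality, for which no direct measure was used.

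The RB-controlled G1/S regulators had 21 of 24 members with a positive fold change, and 9 passed adjusted over the list alone. E2F2, an activating E2F factor, had a log2 fold change of 1.63 ± 0.42 (SE), E2F7 1.07 ± 0.29 and the RB relative RBL1 0.69 ± 0.23. Camera with the preset correlation gave an adjusted p = 3.6e-08, and adjusted p = 0.437 with an estimated correlation. In homologous recombination and Fanconi repair, all 24 members had a positive fold change and RAD54L, with 1.23 ± 0.29, passed adjusted over the list alone, while FANCB had 1.01 ± 0.32. That list had an adjusted p = 3.0e-07 in camera, and adjusted p = 0.517 with an estimated correlation. The mitosis list had 33 of 34 members with a positive fold change and the replication-dependent histones 40 of 40, but 0 members of either passed adjusted over the list alone. In these lists the kinesins KIF2C and KIF4A had log2 fold changes of 1.00 ± 0.33 and 0.70 ± 0.30, and the histone genes H4C3 and H3C2 0.72 ± 0.24 and 1.13 ± 0.38. Both lists passed camera with the preset correlation (adjusted p = 1.1e-06 and 2.3e-06), and their adjusted p = 0.636 with an estimated correlation. Permuting the tumours gave p = 0.0139 for the G1/S, 0.0345 for the repair, 0.150 for the mitosis and 0.158 for the histone list. After adjustment these were 0.122, 0.241, 0.553 and 0.553. With 1 surrogate variable the log2 fold changes of E2F2, KIF2C, KIF4A and H3C2 were 1.01, 0.64, 0.39 and 0.64.

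CDKN2A encodes p16, a protein used in pathology as a surrogate of high-risk HPV. Its RNA did not differ by more than the spread between tumours. The gene lies on chromosome 9 from 21967753 to 21995301 on the minus strand, and the counts per gene do not part its p16 and p14ARF transcripts. Mean log2(CPM + 1) was 6.25 ± 1.28 (SD, n = 12) in HPV-positive and 5.68 ± 1.73 (SD, n = 11) in HPV-negative tumours. The difference was 0.57 with a 95% interval from -0.75 to 1.88 (two-sided permutation test, p = 0.404). Levels ranged from 8.81 to 215.8 CPM in HPV-positive and from 1.14 to 171.1 CPM in HPV-negative tumours. Leaving out the HPV-negative tumour with the lowest level brought the difference to 0.11 (permutation test, p = 0.820). Leaving out 1 HPV-positive tumour brought it to 0.83 (permutation test, p = 0.173).

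Of the other genes fixed before the data were examined and reported here, none passed the adjusted threshold. The cell cycle inhibitor CDKN1A and the ubiquitin ligase MDM2 had log2 fold changes of 0.10 ± 0.24 (SE) and -0.27 ± 0.31. The proliferation marker MKI67 had 0.27 ± 0.28, the growth factor receptor EGFR -0.61 ± 0.47, the checkpoint ligand CD274 -0.46 ± 0.51 and the kinase subunit PIK3CA 0.23 ± 0.15. Under the alternatives fixed beforehand MKI67 lay between 0.06 and 0.35, EGFR between -0.95 and -0.23, CD274 between -1.07 and -0.14 and PIK3CA between 0.14 and 0.30.

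Neutrophil markers and chemoattractants were lower in HPV-positive tumours, with a median log2 fold change of -0.93. Of 17 members 16 had a negative fold change, and 3 passed adjusted over the list alone. These were the G-CSF receptor CSF3R at -1.14 ± 0.33 (SE), CXCL8 at -1.77 ± 0.53 and the neutrophil Fc receptor FCGR3B at -1.29 ± 0.45. All 12 HPV-positive tumours lay below the HPV-negative median of the list mean (2.66 ± 0.78 against 3.59 ± 0.72 log2 CPM, SD, permutation test, p = 0.00787, adjusted p = 0.122). Camera with the preset correlation gave an adjusted p = 1.4e-08, and adjusted p = 0.286 with an estimated correlation. The partial EMT and invasion list had 21 of 22 members with a negative fold change, led by the matrix metalloprotease MMP3 at -1.27 ± 0.45, and the transcription factor ZEB2 was at -0.54 ± 0.24, or -0.28 with 1 surrogate variable. The EMT list passed camera with the preset correlation (adjusted p = 5.7e-06), and its adjusted p = 0.437 with an estimated correlation. Permuting the tumours gave p = 0.0856 for its mean, or 0.500 after adjustment.

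Other leukocyte and stromal lists were lower by the preset correlation, and none of their members passed adjusted over the list alone. The interferon response list had 25 of 28 members with a negative fold change, with GBP5 at -1.22 ± 0.63 (SE) and OASL at -0.75 ± 0.43. T and NK cell markers had 26 of 27, with the NK receptor KLRD1 at -1.35 ± 0.46 and CD8B at -1.19 ± 0.57. MHC class II presentation had 11 of 12, with HLA-DMB at -0.74 ± 0.25 and HLA-DQB1 at -0.62 ± 0.41. Macrophage and dendritic cell markers had 15 of 20, with CD207, the langerin of Langerhans cells, in the other direction at 1.19 ± 0.53 and ITGAX at -0.61 ± 0.27. Fibroblast and matrix genes had 18 of 28, with INHBA at -1.01 ± 0.47 and FN1 at -0.75 ± 0.44. Camera with the preset correlation gave adjusted p = 1.2e-04, 0.0431, 0.0279, 0.0111 and 0.00223 for these 5 lists in that order, and adjusted p = 0.636, 0.783, 0.636, 0.636 and 0.636 with an estimated correlation. Permuting the tumours gave p = 0.348 or more for each of the 5. With 1 surrogate variable none of the 5 was called (adjusted p = 0.127 to 0.393), and with upper quartile factors T and NK cell markers had an adjusted p of 0.0525. Under the alternatives fixed beforehand the log2 fold change of CD8B lay between -1.56 and -0.26, of KLRD1 between -1.80 and -0.57, of GBP5 between -2.25 and -0.32, of HLA-DQB1 between -1.05 and -0.49 and of FN1 between -1.24 and -0.61.

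Genes of the 11q13 region, a segment often gained in squamous carcinomas, were lower in HPV-positive tumours by a median of -1.73 on the log2 scale. All 7 tested members had a negative fold change and 6 passed adjusted over the list alone. CCND1, the G1 cyclin, had -1.35 ± 0.45 (SE), PPFIA1 -1.73 ± 0.53 and the scaffold gene SHANK2 -3.07 ± 0.94. The folds of SHANK2 and PPFIA1 were -1.43 and -0.65 with DESeq2. Median levels were 27.6 CPM in HPV-positive and 29.4 CPM in HPV-negative tumours for SHANK2, and 117.8 and 134.4 CPM for PPFIA1. CCND1 lies on chromosome 11 from 69641087 to 69654474 on the plus strand, and averaged 95.8 ± 59.2 CPM in HPV-positive and 243.6 ± 286.0 CPM in HPV-negative tumours. The mean log2 CPM of the list differed by -0.69 ± 0.48 (SE, permutation test, p = 0.201). Without a single HPV-negative tumour this difference was -0.34 ± 0.37, and the group medians differed by -0.13. Camera with the preset correlation gave an adjusted p = 0.00204, and adjusted p = 0.636 with an estimated correlation. The 3q26-q28 genes had 14 of 16 members with a positive fold change, with GNB4 at 0.45 ± 0.19 (0.19 with log2 library size as a covariate) and ECT2 at 0.61 ± 0.29, and 0 passed adjusted over the list alone. That list passed camera with the preset correlation (adjusted p = 0.0412), and its adjusted p = 0.636 with an estimated correlation and 0.0575 with quality weights. Permuting the tumours gave p = 0.151 for its mean, or 0.553 after adjustment.

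**Figure D2:**
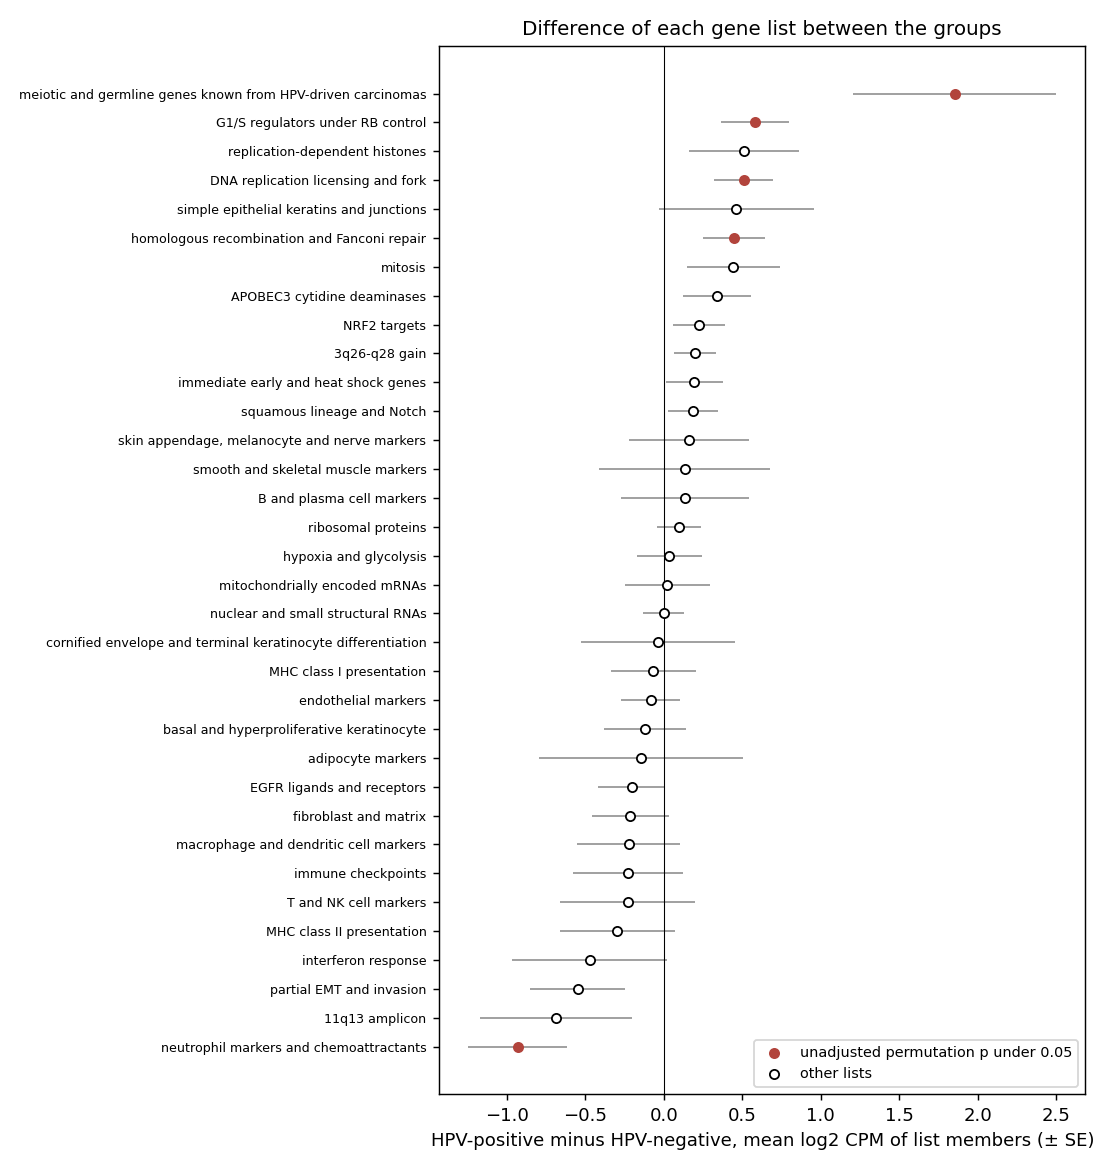
Difference of the mean log2 CPM of each gene list reported, HPV-positive minus HPV-negative, on the horizontal axis with its SE (n = 12 and 11). Red points have an unadjusted permutation p under 0.05, and these are the meiotic, G1/S, replication, homologous recombination and neutrophil lists. None passed after adjustment over the 35 lists, where the smallest adjusted p was 0.122.

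Of 43 cornified envelope genes, markers of keratinocyte differentiation, 22 had a positive fold change. The list was not called by camera with the preset correlation (adjusted p = 0.550), but was called lower with quality weights (adjusted p = 0.00371) and with 1 surrogate variable (adjusted p = 0.0105), all at the preset correlation. Its adjusted p = 0.917 with an estimated correlation, which was run without quality weights or covariates for this and all other lists. RPTN was at -2.16 ± 0.74 (SE), and at -0.96 as a difference of mean log2 CPM. CALML5 was at 0.96 ± 0.41, and at 0.54 with quality weights and 0.46 with 1 surrogate variable. The basal and hyperproliferative keratinocyte list (adjusted p = 0.281) had 14 of 23 members with a negative fold change and a median of -0.25, and was called lower with 1 surrogate variable (adjusted p = 0.0236). Its adjusted p = 0.822 with an estimated correlation. In it KRT15, a basal keratin, was at 1.39 ± 0.43, SERPINB4 at 0.98 ± 0.43 and KRT6B, a keratin of hyperproliferative epithelium, at -1.03 ± 0.49. Squamous lineage and Notch genes had an adjusted p of 0.124 in camera, with NOTCH3 at 0.71 ± 0.24 and NOTCH2 at 0.31 ± 0.15 (0.19 with quality weights). Simple epithelial keratins and junctions had an adjusted p of 0.150 in camera, and 0.0352 with quality weights, higher in HPV-positive tumours, against an adjusted p = 0.686 with an estimated correlation. In that list KRT7, a keratin of glandular and transitional epithelium, averaged 33.0 ± 53.7 CPM (SD, n = 12) against 4.34 ± 2.92 CPM (SD, n = 11), with medians of 6.55 and 4.25 CPM. It alone passed adjusted over the list alone (log2 fold change 2.92 ± 0.83). The difference of KRT7 was 1.80 with quality weights and 1.44 as a difference of mean log2 CPM, and 4 HPV-negative tumours lay above the HPV-positive median. The APOBEC3 list had an adjusted p of 0.312 in camera, and APOBEC3B, a cytidine deaminase, passed adjusted over the list alone at 1.52 ± 0.51, with all 12 HPV-positive tumours above the HPV-negative median. APOBEC3C was at 0.29 ± 0.21, and at 0.06 with log2 library size as a covariate. The list of EGFR ligands, receptors and downstream response genes had an adjusted p of 0.103 in camera. It had 0.0255 with quality weights, lower in HPV-positive tumours, against an adjusted p = 0.636 with an estimated correlation. In it the ligand AREG was at -0.81 ± 0.39 and the response gene DUSP6 at -0.57 ± 0.28.

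The remaining lists were not called by camera with the preset correlation. Camera gave adjusted p = 0.103 for immune checkpoints, for ribosomal proteins and for immediate early and heat shock genes. NRF2 targets had 0.144, endothelial markers 0.130, MHC class I presentation 0.418, hypoxia and glycolysis 0.538 and adipocyte markers 0.518 as adjusted p in camera. With quality weights endothelial markers (adjusted p = 0.000167) and immune checkpoints (adjusted p = 0.0243) were called lower and immediate early and heat shock genes higher (adjusted p = 0.0432). With an estimated correlation these 3 lists had adjusted p = 0.709, 0.686 and 0.636 in that order. B and plasma cell markers had 13 of 19 members with a positive fold change, a median of 0.29 and an adjusted p of 0.548 in camera. Among them CD22 was at -0.85 ± 0.37 (SE), BLK at -1.06 ± 0.49 (-0.67 as a difference of mean log2 CPM) and the immunoglobulin constant region IGHG3 at 1.10 ± 0.56. Smooth and skeletal muscle markers had an adjusted p of 0.550, and were called higher with 1 surrogate variable (adjusted p = 0.0236), against an adjusted p = 0.902 with an estimated correlation. Skin appendage, melanocyte and nerve markers had an adjusted p of 0.876, mitochondrially encoded mRNAs 0.995 and nuclear and small structural RNAs 0.479. Among the last, MALAT1, a nuclear non-coding RNA, took 5.06 ± 2.25% (SD, n = 12) of counts in HPV-positive and 7.06 ± 1.80% (SD, n = 11) in HPV-negative tumours (permutation test, p = 0.0306, adjusted p = 0.188 over 15 library measures). For hypoxia and glycolysis the median fold change of -0.06 and the mean of 0.01 differed in sign. For mitochondrially encoded mRNAs the median was 0.03 and the mean -0.04. The cornified list had a positive median of 0.04 while camera's direction was down. Erythrocyte and platelet markers had 4 tested members and the chromosome X cancer-testis antigens 1, too few to test as lists. The 4 erythrocyte and platelet genes had a median log2 fold change of 0.35, and the cancer-testis antigen MAGEA4 had -0.40 ± 1.18.

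HPV status accounted for 6.02% of the variance of log2 expression between tumours over all tested genes, where relabelled tumours gave a median of 4.38% (permutation test, p = 0.0686). The first principal component held 14.0% of the variance and the second 11.6%, and neither parted the groups (permutation p = 0.108 and 0.433). The third held 9.11% and did not part them either (permutation p = 0.269). It correlated with the percent of reads in genes at r = 0.65, against 0.08 and 0.05 for the first and second. Across the 23 tumours the replication list score bore no relation to the cornified envelope score (Pearson r = -0.00, permutation p = 0.988, adjusted p = 0.988; Spearman's coefficient = 0.07, p = 0.768, adjusted p = 0.768). Within HPV-negative tumours r was -0.48 (p = 0.160) and within HPV-positive tumours 0.30 (p = 0.350), both by permutation, and r was -0.15 (p = 0.539) without the 2 tumours farthest from the median replication score. T and NK cell markers and MHC class II genes rose and fell together across tumours (Pearson r = 0.91, Spearman's coefficient = 0.94). Both had a permutation p of 1e-05, the smallest that 100000 resamples can give, and 2e-05 after adjustment over the 2 relations. This relation was present within HPV-negative tumours (r = 0.95, n = 11, permutation p = 2e-05) and within HPV-positive tumours (r = 0.89, n = 12, permutation p = 4e-05), and r was 0.87 without the 2 tumours farthest from the median T and NK score.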

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

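The tests with the percent of reads in genes, with tumours left out and with permuted list means were chosen after seeing the data. The count of 0 genes in each direction held under 11 of the 12 alternatives fixed beforehand, and DESeq2 gave 35 higher and 8 lower. With the percent of reads in genes as a covariate edgeR gave 16 higher and 1 lower. Leaving out each tumour in turn gave 0 to 2 genes higher and 0 to 1 lower, the calls coming without 1 HPV-positive tumour. Without the 2 tumours with over 8% unaligned reads edgeR gave 0 and 0, and DESeq2 57 and 14. The cause was not tested for any of these. The 7 lists higher and 8 lower became 0 and 0 with the estimated correlation, with fry and by permuting the tumours. The preset correlation of 0.01 lay below the estimated one of each of these lists. Lists lower were 12 with quality weights and 5 with 1 surrogate variable, which kept the neutrophil, EMT and 11q13 lists and added the cornified and basal lists, and 2 when counted by members adjusted over the list alone, and the cause was not tested. Leaving out each tumour gave 6 to 9 lists higher and 5 to 11 lower. The CDKN2A difference lay between 0.11 and 0.83 without each tumour in turn and missed the threshold each time. The variance share lay between 5.71% and 6.23%. The replication and cornified relation was 0.30 within HPV-positive tumours, opposite in sign to the pooled value. Of 69 named genes, CDKN1A turned to -0.0121 with 1 surrogate variable, and MDM2 to 0.0935 with quality weights and 0.189 with the percent of reads in genes as a covariate. MAGEA4 turned to 0.484 with quality weights, 0.333 as a difference of mean log2 CPM, 0.389 with 1 surrogate variable and 0.292 with the T and NK cell score. Lists not called turned direction at adjusted p of 0.920 for MHC class I, 0.876 for adipocyte markers and 0.992 for squamous lineage and Notch with 1 surrogate variable. With quality weights these were 0.930 for B and plasma cells, 0.607 for skin appendages and 0.237 for mitochondrial mRNAs. The cause was not tested. Of 897 values of named genes under alternatives, 871 kept direction and stayed uncalled, 19 newly passed the threshold and 7 turned direction. Since no named gene was called in the main test, staying uncalled says little, and a smaller fold counts as kept. Of 175 values of lists, 123 kept direction and side of the threshold, 37 lost the call, 9 newly passed and 6 turned direction. With 7358592 to 14353034 counts per tumour, 2-fold changes were recovered for 44% of simulated genes.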

Other observations

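The tests of tumour cell share and of the count of edgeR calls were chosen only after the result was seen, as was the covariate for reads in genes. With the percent of reads in genes as a covariate, a rough stand-in for library quality, edgeR called 16 genes higher and 1 lower, of which 9 were also among the 43 called by DESeq2. Among these, SYCP2 had a log2 fold change of 4.06 (adjusted p = 0.0258) and KCNS1 4.08 (adjusted p = 0.0473). RNF212, which acts in meiotic crossing over, had 4.04, against 1.46 ± 0.86 (SE) and an adjusted p of 0.655 without the covariate. ZYG11A, a substrate adaptor of a ubiquitin ligase, had 4.55, against 2.28 ± 0.81 and an adjusted p of 0.425 without it. DESeq2 called neither RNF212 nor ZYG11A. CTSC, a protease that activates neutrophil serine proteases, was the gene called lower, at -1.13 (adjusted p = 0.0473). RNF212, ZYG11A and CTSC were chosen after their values were seen, and this covariate was chosen after seeing the data.

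Other splits of the 23 tumours tested whether chance can be excluded for the counts of calls. Of 100 splits, the real one included, 58 called at least 7 lists higher and 41 at least 8 lists lower with the preset correlation, with 16 and 15 the highest of the other splits. Chance cannot be excluded for these counts. The same holds for the 1692 genes at an unadjusted p under 0.05, which 7 of 100 splits reached, the real one included, with 2453 the highest of the others. It also holds for the 43 genes of DESeq2, which 3 of 40 splits reached, the real one included, with 52 the highest of the others. For the 0 genes of edgeR the test says nothing, since a count of 0 is reached in all 100 splits whatever the data, and the highest of the others was 1.

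The higher replication list was set against 3 technical explanations. With log2 library size as a covariate the difference was 0.55 ± 0.21 (SE), and with the percent of reads in genes it was 0.57 ± 0.21. Neither depth nor this share of reads, a rough stand-in for RNA quality, accounts for the whole. The basal keratinocyte list, which a higher share of tumour cells might raise, lay below the replication list by 0.63 ± 0.30. Its members, 9 higher and 14 lower, had a median fold of -0.25 (SD 0.62) against 0.55. With KRT15 at 1.39 and KRT6B at -1.03, this list does not measure tumour cell share alone, so the test cannot decide. Tumour cell share stays open. The T and NK (-0.23 ± 0.43), macrophage (-0.22 ± 0.33), fibroblast (-0.21 ± 0.25) and endothelial (-0.08 ± 0.19) lists lay lower, each within 1 SE of 0. The B and plasma cell list lay higher (0.13 ± 0.41), also within 1 SE of 0. HPV status stays open, as does chance, since the permutation p of 0.0137 was 0.122 after adjustment.

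The difference of CDKN2A between the groups did not exceed the spread between tumours. Its 95% interval, from -0.75 to 1.88, does not exclude a sizeable difference. For the lack of a clear difference 2 explanations were tested. Within the groups CDKN2A and the meiotic list score rose together (Pearson r = 0.44, 95% interval 0.02 to 0.73), as swapped labels would give. The lower bound lies close to 0. In 1 HPV-negative tumour CDKN2A was at 1.14 CPM, where the next lowest of that group was at 31.8 CPM. The relation was not computed by ranks or without that tumour, so it may rest on it. HPV activity that differs between tumours of a group, CDKN2A raised without HPV, or tumour cell share that varies within a group might give the same relation. These were not tested. A lower share of tumour cells in HPV-positive tumours cannot be told apart, since 5 non-epithelial lists together differed by -0.12 ± 0.22 (SE).

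The lower 11q13 list may rest on few tumours. Without the HPV-negative tumour whose absence weakened it most, the difference was -0.34 ± 0.37 (SE), within 1 SE of 0, and the group medians differed by -0.13. The other 3 tested genes in the window followed the list score (median r = 0.74), but all lie within 5 kb of a list member and can share its reads. A shared level of neighbouring genes therefore cannot be told apart from shared reads.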
